A study of Mus musculus with 12 samples.

How the data were processed

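RNA sequencing counts from 12 libraries of mouse nasal tissue were analysed, 4 for vehicle (PBS, labelled day 10), 4 for KDP20 at day 5 and 4 for KDP20 at day 10. Per the labels, the mice were C57BL/6 males of 6 weeks, RNA was extracted with an RNeasy kit, and libraries were made from total RNA with a SMARTER mRNA-Seq kit. Vehicle libraries carry replicate numbers 2, 4, 5 and 6, day 5 libraries 5, 6, 7 and 8, and day 10 libraries 1, 2, 3 and 5. The labels do not state that every library came from a separate animal, so p-values measure the spread between these samples.

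Per the submitters' processing notes, the authors checked reads with FastQC, trimmed them with Trim Galore, aligned them to mm10 with STAR and made a table of gene counts with HTSeq, and the deposited unit is counts. Tool versions, the annotation release, the counting mode and the strand setting are not given in the sources used here. The table held 55487 gene rows, of which 21025 were 0 in every library. Of these, 55227 identifiers were found in GENCODE M21, 53417 also carried the same symbol, and 120 symbols were shared by more than 1 row. The 37 mitochondrial rows held 0 counts in all 12 libraries.

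Each row was placed in GENCODE M21 with bedtools 2.31.1 and Python 3.11.15. A row was called opposite to a gene when its exons overlapped exons of that gene on the other strand by at least 50 bases, which held for 8380 rows. Because the strand setting is unknown, such rows are given with the opposite gene at first mention, and a count there need not come from the gene that names the row.

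Rows were filtered with filterByExpr, scaled with TMM and tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with group as the sole term and all 12 libraries in 1 model. The filter left 13181 rows, which held 98.3% of all counts, and the common biological coefficient of variation was 0.213. Calls used a Benjamini-Hochberg adjusted p under 0.05 over the tested rows. Standard errors were derived from the log2 fold change and its F statistic. Errors beside group means are SDs over 4 libraries, in edgeR CPM of the TMM-scaled library size.

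Depth per library ran from 1658420 to 3227138 counts, so the detection floor of 3 counts lay between 0.930 and 1.81 CPM of the unscaled totals. Pairs of replicates differed by 3.18 to 22.6 times the variance that counting alone gives, over 18 pairs. The pipeline was tested in 1 run on simulated data at the depth and spread of these libraries. For day 10 against vehicle it recovered 47% of 100 planted 2-fold changes and 88% of 100 planted 4-fold changes, and 4.26% of its calls were false. Rows were drawn independently, so false calls from differences in library composition shared between rows were not tested.

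The comparisons were day 10 against vehicle, day 5 against vehicle and day 10 against day 5. The first is matched on day. In the second, exposure and day of collection differ together, because vehicle was labelled day 10 alone. There were 40 fixed gene lists for pathways, cell types, other tissues and technical signals, tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Library measures were compared by exact permutation of the 8 libraries, with Benjamini-Hochberg over 15 tests.

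The comparisons, tests, lists, 15 sentinel genes and the naming rule were fixed before the data were examined. The rule names, among calls with a mean log2 CPM of at least 1 and no overlap between the groups, the 12 with the largest rise and the 12 with the largest fall, skipping unnamed gene models. It also names the sentinel genes and up to 4 members with the smallest p of each described list. Exceptions were chosen after their values were seen: the 12 rows in each direction that lie opposite a protein-coding gene, the reading of the fixed lists through opposite rows, and rows named from small counts or from calls at both days.

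The alternatives fixed in advance were the scaling of DESeq2 1.42.0 and upper-quartile scaling, no filter and a filter of 10 CPM in 4 libraries, the DESeq2 and limma-voom tests, the 8 compared libraries alone, the replicate number as a block and leaving out each library. Alternatives added after seeing the data were a GC correction of each library (loess, span 0.5, for the 99.8% of tested rows with a GC content), the share of the row CT010467.2 as a covariate, leaving out that row's clone and satellite rows, rows opposite protein-coding genes alone, and leaving out 3 day 10 libraries. Cell-cycle genes for a further test came from Seurat 5.3.0. The pseudocount alternative did not apply, since the values were counts. Some results that the naming rule selects are not reported here. No library was left out of the reported comparisons.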

Results

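Gene counts were measured in nasal tissue from 3 groups of 4 mouse libraries, namely vehicle at day 10, KDP20 at day 5 and KDP20 at day 10. The series title asks how diesel particles alter gene expression in nasal inflammatory dysfunction. Mean depth was 2379520 counts for vehicle, 2196850 for day 5 and 1830010 for day 10. Floors and intervals below cover counting error alone.

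Own rows of several abundant airway and housekeeping genes held few counts, and rows on the strand opposite to Cyp2f2 and Malat1 held many. Cyp2f2, a cytochrome P450 of airway secretory cells, had 46 to 331 counts per library in its own row, against 27656 to 84309 in the row of Gm15883, which lies opposite to it. Malat1, an abundant nuclear RNA, had 200 to 1726 counts against 35723 to 102465 for the opposite row Gm37376. Actb, a cytoskeletal actin, had 23 to 217 counts, and the 83 ribosomal protein genes together held 0.103% to 0.149% of counts in their own rows. Rows with an opposite exon held 54.9% to 69.4% of counts, and the 95% Wilson intervals of these shares reached at most 0.0751 points to each side. Changes are given first for genes by their own rows, and then for rows that lie opposite to a named gene. In neither case is the strand of the counted RNA settled, so a change in a gene's own row need not be a change of its mRNA.

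**Figure D1:**
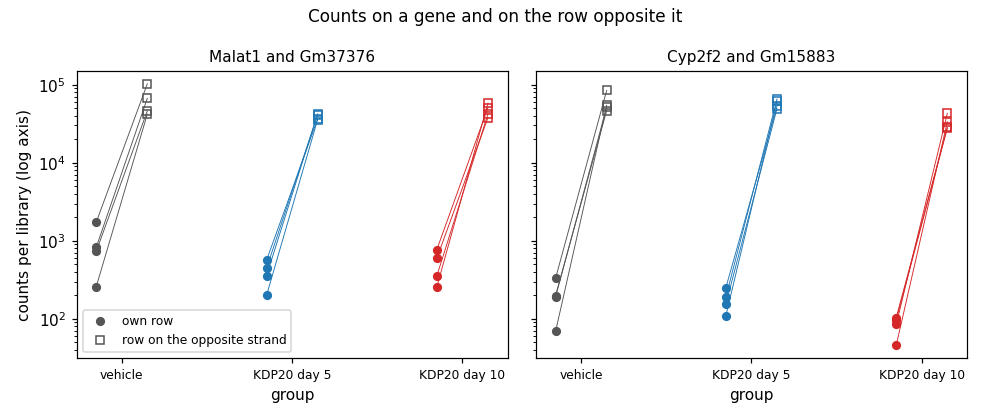
Counts per library on a log scale for Malat1 and Cyp2f2 in their own rows and in the opposite rows Gm37376 and Gm15883. Lines join the same library, with 4 libraries per group.

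The row CT010467.2 took 19.4% ± 6.32 of counts at day 10, against 8.66% ± 1.55 for vehicle and 10.9% ± 1.33 at day 5 (mean ± SD, n = 4). Its identifier is missing from the annotation used here, and it is read as ribosomal RNA from its clone name, which could not be tested. In day 10 replicates 1, 2, 3 and 5 its share was 11.2%, 25.5%, 17.9% and 22.9%, with Wilson intervals of at most 0.0658 points to each side. By exact permutation, day 10 exceeded vehicle with p 0.0286, the smallest that 4 against 4 can give, and an adjusted p of 0.0779. Each row's log2 CPM, as its deviation from the row's mean over the 12 libraries, was also fitted on GC content. This relative slope was 0.201 per 10 points at day 10, -0.137 for vehicle and -0.0648 at day 5. Exact permutation gave the same p for day 10 against vehicle. Day 10 replicate 1 had a slope of -0.0516, while replicates 2, 3 and 5 had 0.371, 0.205 and 0.282. The first principal component held 26.5% of the variance and set replicates 2, 3 and 5 of day 10 apart from the other 9 libraries.

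**Figure D2:**
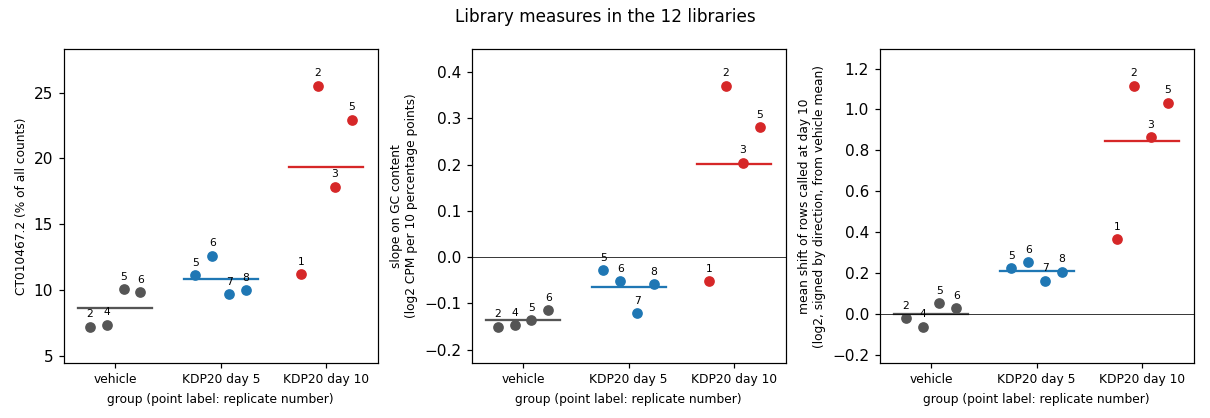
Each library's share of counts in CT010467.2, its slope on GC content, and the mean shift of rows called between day 10 and vehicle, signed by the direction of the call. The slope is of log2 CPM relative to each row's mean over the 12 libraries. Labels are replicate numbers and lines are group means.

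At day 10 against vehicle, the own rows of some odorant-binding, gland and olfactory receptor genes were lower in KDP20 mice. With the strand of the counted RNA not settled, these rows need not report the mRNA of those genes. By own rows, edgeR called 0 of 12 olfactory sensory neuron genes (median 0.08), 0 of 9 airway secretory genes and 0 of 8 mucus genes. A gene without a call in its own row need not be unchanged, since the row opposite Gnal, a listed neuron gene, was called lower. Obp2a, an odorant-binding protein, fell to 179 ± 103 from 466 ± 180 CPM (log2 fold change -1.38, SE 0.37, edgeR adjusted p 0.0270). It was the single call among 9 genes of sustentacular cells and Bowman glands, which had a median of -0.58 and a camera adjusted p of 0.281 (0.950 with an estimated correlation). The mean log2 CPM of these 9 was 4.18 in day 10 replicate 5 and 5.00 to 5.03 in the other day 10 libraries. Bpifb6 (-1.72, SE 0.47, adjusted p 0.0311), Bpifb3 (-1.32, SE 0.38, 0.0379), the lipocalin Lcn4 (-1.55, SE 0.45, 0.0392) and Obp1b (-1.29, SE 0.38, 0.0430) also fell. Among olfactory receptor genes, Olfr1396 (-1.89, SE 0.57, adjusted p 0.0466), Olfr615 (opposite Olfr616, -0.89, SE 0.27, 0.0484) and the pseudogene Olfr856-ps1 (-1.21, SE 0.35, 0.0379) fell, as did the vomeronasal receptor Vmn1r184 (-0.99, SE 0.29, 0.0398). The 24 tested olfactory receptor genes had a median log2 fold change of -0.57, with 22 negative, 3 called lower over all rows and 3 over the list alone. Camera gave them an adjusted p of 0.00322 and fry 0.0269, but camera with an estimated correlation gave an adjusted p of 0.428. Their mean log2 CPM was 3.25 in day 10 replicate 1 and 2.60 to 2.91 in the other day 10 libraries. Those other libraries held the largest shares of CT010467.2. It was 3.39 to 3.54 in vehicle and 3.06 to 3.39 at day 5. The 7 rows opposite olfactory receptor genes had a median of -0.51, with 6 negative, 1 called lower and a camera adjusted p of 0.459. List tests with GC correction or the CT010467.2 covariate are not given here. The 13 nasal gland and odorant-binding genes had a median of -0.85, 4 calls lower, 7 over the list alone, and a camera adjusted p of 0.0614 (0.950 with an estimated correlation). This list leaned on day 10 replicate 5, without which the difference of mean log2 CPM went from -0.72 to -0.43.

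Other genes called at day 10 came singly from their lists, and no such list that was large enough for camera passed it. Lor, a protein of the cornified envelope, rose to 93.8 ± 24.9 from 43.2 ± 16.7 CPM (log2 fold change 1.13, SE 0.23, edgeR adjusted p 0.00824). Mmp9, a matrix metalloproteinase made by neutrophils among other cells, rose to 245 ± 38.0 from 161 ± 26.1 CPM (0.61, SE 0.15, 0.0189). Slc30a1, a zinc exporter that lies opposite 1700034H15Rik, rose to 21.8 ± 7.67 from 8.91 ± 3.05 CPM (1.30, SE 0.31, 0.0167). Hdc, which makes histamine, rose to 255 ± 41.0 from 181 ± 33.2 CPM (0.49, SE 0.15, 0.0496), and the antigen-presentation gene H2-DMa, opposite Brd2, rose by 0.60 (SE 0.16, 0.0247). Cd247, the zeta chain of the T cell receptor, which lies opposite Pou2f1, fell to 267 ± 74.1 from 370 ± 12.8 CPM (-0.47, SE 0.14, 0.0468). Ccdc39, needed for beating cilia and opposite Ttc14, fell to 137 ± 74.3 from 243 ± 11.5 CPM (-0.83, SE 0.21, 0.0221), as the single call among 13 ciliated-cell genes. The calcium pump of fast muscle Atp2a1 (opposite Rabep2, 0.57, SE 0.16, 0.0385), the erythroid factor Klf1 (0.97, SE 0.29, 0.0441) and the neuronal receptor Grin1 (opposite Grin1os, 0.45, SE 0.11, 0.0189) rose.

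Among genes picked by the fixed naming rule, the rises between day 10 and vehicle included Edem1, which directs misfolded glycoproteins to degradation (6.88 ± 1.25 against 1.63 ± 0.918 CPM, log2 fold change 2.01, SE 0.54, edgeR adjusted p 0.0268), Phf23 (1.97, SE 0.43, 0.0106) and the kinase Pim3 (1.85, SE 0.49, 0.0247). The microtubule-regulating kinases Mark4 (1.65, SE 0.48, 0.0379) and Mark3 (1.35, SE 0.33, 0.0186) also rose. So did the ectoenzyme Enpp1 (1.65, SE 0.41, 0.0192), Rusc1 (1.58, SE 0.44, 0.0328), the convertase Pcsk4 (1.5, SE 0.43, 0.0355), Ajm1 (opposite Gm26702, 1.43, SE 0.32, 0.0126), Fam43a (1.42, SE 0.42, 0.0424), the fucosyltransferase Fut4 (1.37, SE 0.41, 0.0438) and CT010467.2 (1.39, SE 0.22, 0.00500). Taldo1, the transaldolase of the pentose phosphate pathway, fell the most among genes named by their own rows (0.972 ± 0.863 against 5.61 ± 2.05 CPM, -2.40, SE 0.62, 0.0222). The ribosomal protein gene Rps3a1 (-1.71, SE 0.49, 0.0354) and the mitochondrial ribosomal gene Mrps35 (-1.68, SE 0.35, 0.00880) fell. The ubiquitin-activating enzyme Uba6 fell to 11.3 ± 6.41 from 36.1 ± 3.29 CPM (-1.64, SE 0.29, 0.00500), and the adiponectin receptor Adipor2 by 1.56 on the log2 scale (SE 0.38, 0.0169). Dipk1c (opposite D030046N08Rik, -2.20, SE 0.66, 0.0442), Lyrm2 (-2.05, SE 0.56, 0.0286), Lrrc18 (-1.76, SE 0.43, 0.0167), Zfp711 (-1.64, SE 0.41, 0.0192), the spindle gene Knstrn (opposite Gm14091, -1.58, SE 0.47, 0.0438) and Pter (-1.48, SE 0.28, 0.00608) fell too. Several of these means lie close to the detection floor.

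Of the 15 sentinel genes, 6 had enough counts to test, and none was called between day 10 and vehicle by edgeR. The olfactory marker Omp (21.6 ± 6.33 against 28.1 ± 11.5 CPM, log2 fold change -0.40, adjusted p 0.460), the cytokine Il1b (-0.23, 0.668), the mucins Muc5ac (-0.40, 0.340) and Muc5b (-0.02, 0.953), the cilium regulator Foxj1 (0.08, 0.848) and the junction gene Tjp1 (0.72, 0.403) all missed the threshold. Cyp1a1, Cyp1b1, Nqo1, Hmox1, Il6, Tnf, Cxcl1, Il33 and Tslp had 0 to 17 counts per library in their own rows and were not tested, so their response to KDP20 was not resolved.

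Rows opposite the immune genes Mpo and Eomes were lower at day 10 than in vehicle. The row Gm11505, opposite the neutrophil myeloperoxidase Mpo, had 3 counts over the day 10 libraries and 129 over vehicle, a ratio of 33.1 with a 95% counting interval of 11.1 to 162 (log2 fold change -4.59, SE 0.99, edgeR adjusted p 0.0103). Gm33460, opposite Eomes, a transcription factor of T and NK cells, fell to 3.13 ± 1.40 from 11.9 ± 3.44 CPM (-1.89, SE 0.46, 0.0167). Ccdc152, opposite the selenium carrier Selenop, fell to 148 ± 87.2 from 328 ± 31.4 CPM (-1.14, SE 0.23, 0.00843). Snhg14, opposite the ubiquitin ligase Ube3a, fell as well (-1.06, SE 0.23, 0.0102). The row Mppe1, opposite Gnal, the G protein of odour transduction, fell to 2756 ± 612 from 3972 ± 485 CPM (-0.53, SE 0.15, 0.0338). Gm15587, opposite the endothelial nitric oxide synthase Nos3, rose to 139 ± 44.4 from 60.1 ± 7.76 CPM (1.20, SE 0.19, 0.00500). The row 4931440P22Rik, opposite Tiparp, a target of the aryl hydrocarbon receptor, rose to 40.1 ± 5.38 from 24.7 ± 3.34 CPM (0.70, SE 0.20, 0.0368). Gm28523, opposite the phosphodiesterase Pde3a (1.66, SE 0.50, 0.0467), Gm15918, opposite Xkr6 (1.30, SE 0.23, 0.00500), and Cdk19os, opposite Cdk19 (1.28, SE 0.21, 0.00500), rose as well.

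For day 10 against vehicle, edgeR quasi-likelihood called 933 of 13181 rows after Benjamini-Hochberg, 518 higher and 415 lower, and 3137 had an unadjusted p under 0.05. Of the 3859 tested rows opposite a protein-coding gene, 342 were called higher and 157 lower. This class had a median log2 fold change of 0.08, and rows with no opposite gene -0.09. Of the 933, 538 had no overlap between the groups, as had 9.98% of all tested rows, where chance gives 2.86%. Of 27 tested lists, 1 passed camera (4 at an unadjusted p under 0.05), and with an estimated correlation 0 did. The balance of directions depended on the setting, since edgeR called 340 rows higher and 82 lower with GC correction, and 777 higher and 924 lower with the replicate number as a block. The count depended on single libraries. It was 2684 without day 10 replicate 1 and 466, 192 and 95 without day 10 replicates 3, 2 and 5. It was 337, 399 and 429 without vehicle replicates 2, 4 and 6. Of the 72 named calls of this comparison, 11 held without day 10 replicate 5 and 72 without day 10 replicate 1, and none changed direction when a library was left out. With the CT010467.2 share as a covariate, edgeR called 0 rows (409 at an unadjusted p under 0.05).

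At day 5 against vehicle, rows opposite histone genes, most of them genes transcribed while DNA is copied, were higher in KDP20 mice. Gm44297, opposite Hist1h2af, rose to 153 ± 21.5 from 45.3 ± 6.64 CPM (log2 fold change 1.76, SE 0.16, edgeR adjusted p 9.29e-07). The row 4930558J22Rik, opposite Hist1h4b, rose to 117 ± 13.1 from 50.3 ± 5.06 CPM (1.22, SE 0.15, 0.000221). Rows opposite Hist1h2ab (Gm44484, 1.35, SE 0.23, 0.00615), Hist1h2ak (Gm44454, 0.97, SE 0.15, 0.00329), Hist1h2ae (Gm44394, 1.56, SE 0.35, 0.0384), Hist1h2an (Gm44346, 1.46, SE 0.29, 0.0247), Hist1h2ac (Gm44350, 1.04, SE 0.23, 0.0384) and Hist2h3b (Gm20628, 0.73, SE 0.16, 0.0344) rose too. So did Gm44335, opposite H2afx, a histone outside the fixed list (1.17, SE 0.17, 0.00237). All 14 tested rows opposite listed histone genes were above vehicle, with a median of 1.00, 8 called over all rows and 12 over the list alone. Camera gave an adjusted p of 6.28e-17, camera with an estimated correlation an adjusted p of 0.00386, and fry an adjusted p of 3.12e-05. Camera set these 14 rows against all tested rows, of which those opposite protein-coding genes had a median of 0.18. Over the 12 sets with a library left out, the camera adjusted p stayed between 1.41e-17 and 7.39e-15. The 13 histone genes tested by their own rows gave 0 calls, with a median of 0.27 and a camera adjusted p of 0.524 (unadjusted 0.0583).

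**Figure D3:**
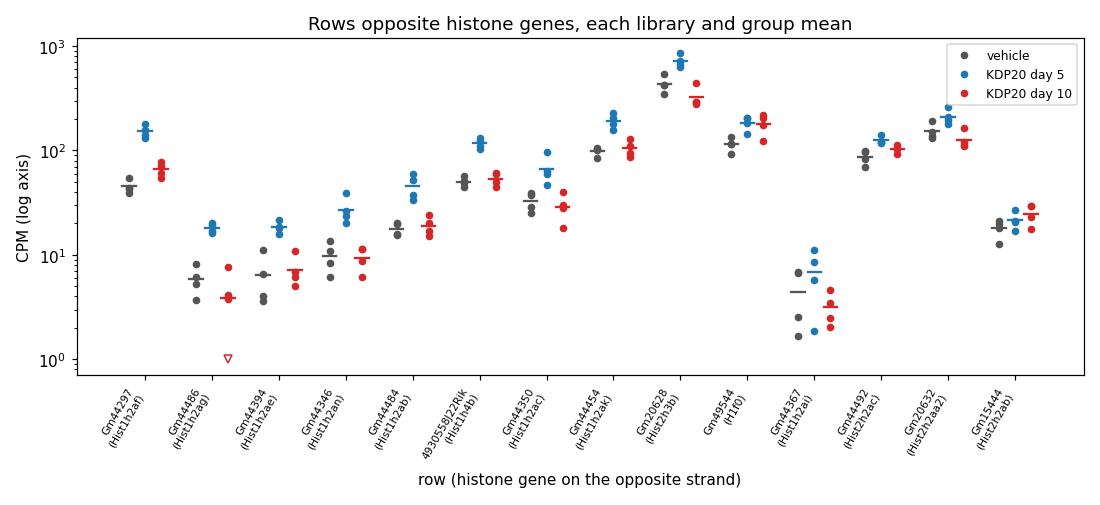
CPM of the 14 tested rows opposite histone genes in each library, on a log scale, with group means. A library at 0, Gm44486 in day 10 replicate 5, is drawn as an open triangle at 1.0 CPM.

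Rows opposite Ncapg, Kif20a, Prc1 and Krt5 were also higher at day 5. Lcorl, opposite the condensin gene Ncapg, rose to 32.9 ± 2.64 from 14.6 ± 3.32 CPM (log2 fold change 1.19, SE 0.23, edgeR adjusted p 0.0198). Cdc23, opposite the mitotic kinesin Kif20a, rose to 72.2 ± 10.4 from 35.6 ± 5.22 CPM (1.02, SE 0.19, 0.0198), and Rccd1, opposite the cytokinesis gene Prc1, to 126 ± 12.0 from 68.6 ± 10.5 CPM (0.88, SE 0.15, 0.0107). Gm10143, opposite the replication nuclease Fen1, rose by 0.66 (SE 0.15, 0.0384). Gm44323, opposite the basal keratin Krt5, rose to 712 ± 293 from 371 ± 109 CPM (0.94, SE 0.22, 0.0469), and Gm10129, opposite desmoplakin Dsp, to 225 ± 23.6 from 153 ± 22.9 CPM (0.56, SE 0.13, 0.0494). Apol7d, opposite fibronectin Fn1, rose to 359 ± 69.4 from 207 ± 47.9 CPM (0.80, SE 0.17, 0.0384). Gm10252, opposite the ferritin light chain Ftl1, rose to 5041 ± 589 from 3340 ± 428 CPM (0.59, SE 0.13, 0.0384), and Gm20496, opposite the immunoproteasome gene Psmb8, by 0.81 (SE 0.18, 0.0384). The 6 rows opposite tissue-remodelling genes had a median of 0.35, 1 call higher, 2 over the list alone, and a camera adjusted p of 0.0396, or 0.263 with an estimated correlation. That camera call was past the threshold in 5 of the 12 sets with a library left out, with adjusted p from 0.0194 to 0.113. Camera set these 6 rows against all tested rows. Rows opposite protein-coding genes had a median of 0.18 as a class, which by itself favours a call higher. Gm48752, opposite the muscle gene Mybpc1 (2.19, SE 0.47, 0.0344), and Gm32312, opposite the muscle hormone Ostn (1.87, SE 0.40, 0.0344), rose. This signal varied between libraries, since the mean log2 CPM of 6 rows opposite muscle genes was 7.53 and 6.81 in day 5 replicates 8 and 6 but 1.91 and 1.77 in replicates 5 and 7.

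By its own row, Arnt, the dimer partner of the aryl hydrocarbon receptor, fell to 3.55 ± 0.845 from 11.5 ± 1.94 CPM (log2 fold change -1.69, SE 0.38, edgeR adjusted p 0.0384). The immune receptors Cd300lf (38.9 ± 8.70 against 72.5 ± 11.8 CPM, -0.90, SE 0.19, 0.0344) and Vsir (54.8 ± 8.56 against 96.9 ± 15.2 CPM, -0.83, SE 0.19, 0.0384) fell. The extracellular matrix gene Hmcn2 (-1.35, SE 0.28, 0.0302), Vmn1r184 (-1.23, SE 0.29, 0.0464), the signalling adaptor Sh2b2 (-1.22, SE 0.27, 0.0384), the antioxidant enzyme Pon2 (opposite Gm44424, -1.08, SE 0.24, 0.0384) and the glycogen phosphorylase Pygl (-0.98, SE 0.22, 0.0384) were lower as well. So were Trim9 (opposite Gm32151, -0.94, SE 0.21, 0.0384), the splicing factor Snu13 (-0.91, SE 0.21, 0.0432), Mtss2 (-0.79, SE 0.18, 0.0384) and Foxn3 (-0.74, SE 0.17, 0.0397). Sox4, a factor of progenitor cells that lies opposite Gm26735, rose to 46.7 ± 6.55 from 26.4 ± 2.46 CPM (0.82, SE 0.18, 0.0384). The phosphatase Ptpre (opposite 5830432E09Rik, 1.37, SE 0.32, 0.0469) and the receptor pseudogene Vmn1r-ps150 (1.44, SE 0.32, 0.0384) rose. Mir1905, opposite Mex3a (1.21, SE 0.23, 0.0198), Slfn5os, opposite Slfn5 (1.03, SE 0.18, 0.0144), Batf2, opposite Arl2 (0.85, SE 0.20, 0.0493), and Nbea, opposite Mab21l1 (0.81, SE 0.17, 0.0302), rose.

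Sentinel genes gave 0 edgeR calls at day 5 against vehicle. Muc5b was at 255 ± 19.4 against 340 ± 42.3 CPM (log2 fold change -0.42, adjusted p 0.105), Foxj1 at 23.1 ± 2.97 against 32.3 ± 6.12 CPM (-0.48, 0.236), Il1b at -0.50 (0.411), Muc5ac at -0.38 (0.479), Omp at -0.25 (0.743) and Tjp1 at 0.42 (0.747). The 13 ciliated-cell genes had a median of -0.31, with 10 negative and none called over all rows, and 1 higher and 3 lower over the list alone. Fry called the ciliated list lower with an adjusted p of 0.0163, while camera gave an adjusted p of 0.524. Unlike camera, fry does not set a list against other rows, and rows with no opposite gene had a median of -0.14 as a class. The 5 rows opposite ciliated-cell genes had a median of 0.0018, with 3 positive and 0 called. For these 5 rows camera gave an adjusted p of 0.738 and fry 0.691. Their mean log2 CPM was 7.43 to 7.58 at day 5 and 7.52 to 7.69 in vehicle.

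For day 5 against vehicle, edgeR quasi-likelihood called 87 rows, 54 higher and 33 lower, and 2144 had an unadjusted p under 0.05. Of those 54 and 33, 48 and 5 lay opposite protein-coding genes, as did 3859 of the 13181 tested rows. The whole class of rows opposite protein-coding genes had a median log2 fold change of 0.18, and rows with no opposite gene -0.14. The directions of the calls thus follow a shift between these classes of rows. No overlap between groups was seen for 82 of the 87 and for 11.7% of tested rows, against 2.86% by chance. Camera passed 0 of 27 lists by own rows (2 at an unadjusted p under 0.05), and fry 1. Leaving out day 5 replicates 5, 6 and 8 left 5, 15 and 24 calls, and vehicle replicates 2, 6 and 4 left 13, 12 and 22. The count was 209 without vehicle replicate 5, 569 without day 10 replicate 1 and 55 without day 10 replicate 3. It was 656 with the 8 compared libraries alone, where day 10 against vehicle had 423, so which comparison called more depended on the fit. DESeq2 called 514 rows and limma-voom 284. The 5 rows left without day 5 replicate 5, chosen after their values were seen, were Gm44297 (log2 fold change 1.74, edgeR adjusted p 1.40e-05), 4930558J22Rik (1.20, 0.00254), Gm44335 (1.17, 0.0140), Gm44454 (0.95, 0.0250) and Gm9996, opposite Soga3 (1.42, 0.0204).

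From day 5 to day 10, rows opposite histone genes fell back. Gm44297, opposite Hist1h2af, fell to 66.4 ± 10.5 from 153 ± 21.5 CPM (log2 fold change -1.20, SE 0.16, edgeR adjusted p 0.000346), Gm20628, opposite Hist2h3b, to 327 ± 80.1 from 719 ± 97.6 CPM (-1.13, SE 0.16, 0.000368), and 4930558J22Rik to 53.7 ± 7.94 from 117 ± 13.1 CPM (-1.13, SE 0.16, 0.000368). Of the 14 rows opposite histone genes, 10 were called lower, also 10 over the list alone. Their median was -1.13, with a camera adjusted p of 2.39e-09, an adjusted p of 0.0280 with an estimated correlation and a fry adjusted p of 7.14e-05. The camera adjusted p stayed between 7.92e-11 and 1.10e-06 with each library left out. At day 10 against vehicle the same 14 rows had a median of 0.10, 2 calls higher (Gm44297, 0.56, adjusted p 0.0423, and Gm49544, opposite H1f0, 0.66, adjusted p 0.0218) and a camera adjusted p of 0.459. Exosc9, opposite the cyclin gene Ccna2, fell to 17.0 ± 8.70 from 58.1 ± 10.99 CPM (-1.75, SE 0.27, 0.000752), and Ccna2 by its own row to 48.2 ± 16.5 from 74.4 ± 10.3 CPM (-0.62, SE 0.19, 0.0414).

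Rows opposite F13a1, Ms4a6c, Cd7 and Krt10 also fell between day 5 and day 10. Gm30489, opposite F13a1, the factor XIII chain of macrophages and platelets, fell to 16.6 ± 9.53 from 79.3 ± 24.5 CPM (log2 fold change -2.23, SE 0.29, edgeR adjusted p 0.000346). BE692007, opposite Ms4a6c (-1.75, SE 0.34, 0.00327), Gm11775, opposite the lymphocyte gene Cd7 (-2.78, SE 0.62, 0.00661), and Gm17711, opposite Abracl (-1.71, SE 0.31, 0.00264), fell. Gm11505, opposite Mpo, had 3 counts at day 10 and 132 at day 5, a ratio of 36.7 with a counting interval of 12.3 to 180 (-4.89, SE 0.97, 0.00373), but 0.504 CPM in day 5 replicate 8. Gm11940, opposite Krt10, fell to 1.21 ± 1.698 from 17.4 ± 10.3 CPM (-3.67, SE 0.75, 0.00448), whereas Lor rose by its own row to 93.8 ± 24.9 from 54.1 ± 6.65 CPM (0.79, SE 0.22, 0.0267). Gm15883, opposite Cyp2f2, fell to 19522 ± 1782 from 26729 ± 2725 CPM (-0.45, SE 0.13, 0.0244), and Muc20, opposite the mucin Muc4, to 261 ± 75.4 from 412 ± 82.1 CPM (-0.66, SE 0.20, 0.0326). Gm13857, opposite Akr1b7 (-2.57, SE 0.54, 0.00467), and Gm48084, opposite the laminin gene Lama2 (-1.64, SE 0.30, 0.00275), fell, while Nphs1os, opposite Nphs1 (1.64, SE 0.26, 0.000904), Gm15917, opposite Tle2 (1.64, SE 0.24, 0.000724), and Gm13561, opposite the peptidase Dpp4 (1.61, SE 0.51, 0.0447), rose.

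By their own rows, Mmp9 rose to 245 ± 38.0 at day 10 from 135 ± 22.4 CPM at day 5 (log2 fold change 0.86, SE 0.15, edgeR adjusted p 0.00222), and Cd247 fell to 267 ± 74.1 from 451 ± 12.7 CPM (-0.75, SE 0.14, 0.00308). The 5 tested neutrophil genes had a median of -0.31 although camera gave a positive direction. The gel-forming mucin Muc5b rose to 336 ± 43.2 from 255 ± 19.4 CPM (0.40, SE 0.13, 0.0483). Own rows of ciliated-cell genes moved both ways, and need not report those genes. Tppp3 (114 ± 11.8 against 60.5 ± 12.3 CPM, 0.91, SE 0.18, 0.00407) and Dnah9 (opposite Gm12296, 0.87, SE 0.18, 0.00428) were higher. Dnah11 (opposite Cdca7l, -0.86, SE 0.21, 0.0101) and Ccdc39 (opposite Ttc14, -0.74, SE 0.21, 0.0280) were lower. Of the nasal gland list, 4 genes were called lower, namely Bpifb3 (-1.74, SE 0.38, 0.00592), Lcn4 (-1.82, SE 0.45, 0.0122), Bpifb6 (-1.64, SE 0.48, 0.0309) and Dmbt1 (-1.09, SE 0.33, 0.0380), as were Obp2a (-1.33, SE 0.37, 0.0246) and the receptor Olfr934 (-0.98, SE 0.30, 0.0375). Ubd, a ubiquitin-like protein induced by interferon gamma and tumour necrosis factor, fell to 5.88 ± 3.69 from 21.9 ± 4.66 CPM (-1.83, SE 0.37, 0.00395). The cartilage gene Acan (-1.78, SE 0.49, 0.0219) and the linker histone H1f3 (-1.49, SE 0.46, 0.0377) fell, and Atp2a1 rose (0.95, SE 0.17, 0.00204). The 13 nasal gland and odorant-binding genes had a median of -0.73, 4 calls lower, 5 over the list alone, and a camera adjusted p of 0.147 (0.766 with an estimated correlation). Without day 10 replicate 5 the difference of their mean log2 CPM went from -0.69 to -0.40.

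Among genes picked by the fixed naming rule, which skips unnamed gene models, the largest rises from day 5 to day 10 were in Slc39a14, a zinc and iron importer (6.40 ± 2.03 against 1.47 ± 1.60 CPM, log2 fold change 2.13, SE 0.64, edgeR adjusted p 0.0346), Pcyt2 (2.08, SE 0.51, 0.0119), the lymphotoxin receptor Ltbr (2.07, SE 0.56, 0.0206) and Rapgef3 (opposite Rapgef3os2, 1.96, SE 0.55, 0.0243). Cald1, a regulator of actin, rose to 33.1 ± 15.03 from 10.5 ± 1.31 CPM (1.63, SE 0.33, 0.00395), and Hmcn2 to 37.1 ± 11.6 from 12.9 ± 3.42 CPM (1.52, SE 0.28, 0.00294). Setbp1 (1.65, SE 0.44, 0.0188), Pcsk4 (1.61, SE 0.44, 0.0212), Atcay (opposite Atcayos, 1.59, SE 0.38, 0.0101), the protease Htra3 (1.57, SE 0.35, 0.00685) and Elmo2 (1.56, SE 0.43, 0.0216) rose too. Among the same genes, falls were largest in Hapln3 (-2.80, SE 0.79, 0.0255), the receptor kinase Ret (-2.26, SE 0.66, 0.0313), Taldo1 (-2.23, SE 0.63, 0.0267), Dipk1c (-2.21, SE 0.66, 0.0344) and Lrrc18 (-2.18, SE 0.42, 0.00337). The sulfate transporter Slc26a2 (-2.07, SE 0.66, 0.0481), Lyrm2 (-2.03, SE 0.56, 0.0238), Hs3st3b1 (-1.92, SE 0.53, 0.0233), the origin-recognition gene Orc2 (opposite Nif3l1, -1.84, SE 0.35, 0.00308) and the mitochondrial ribosomal gene Mrpl57 (-1.83, SE 0.57, 0.0405) fell as well. The other tested sentinels, Foxj1 (0.56, 0.0822), Il1b (0.26, 0.646), Tjp1 (0.30, 0.765), Omp (-0.14, 0.833) and Muc5ac (-0.02, 0.971), were not called.

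For day 10 against day 5, edgeR quasi-likelihood called 1337 rows, 614 higher and 723 lower, and 3252 had an unadjusted p under 0.05. The 3859 tested rows opposite protein-coding genes were called higher 206 times and lower 530 times. As a class they had a median log2 fold change of -0.09, and rows with no opposite gene 0.05. Of the 1337, 922 had no overlap between the groups, as had 12.5% of tested rows, against 2.86% by chance. Camera and fry passed 0 of 27 lists by own rows, with 2 at an unadjusted camera p under 0.05. The count was 2689 without day 10 replicate 1, 677, 629 and 623 without day 10 replicates 3, 2 and 5, and 879, 752, 841 and 871 without day 5 replicates 8, 5, 7 and 6. Of 80 named calls, 49 held without day 10 replicate 2. With the CT010467.2 share as a covariate, 2 of the 1337 rows were called, Gm44297 and 4930558J22Rik, and thus 2 of the 80 named calls, and 1471 had an unadjusted p under 0.05.

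In the fit of all 12 libraries, genes called against vehicle at both days were few. Vmn1r184 fell at both (log2 fold change -1.23 at day 5 and -0.99 at day 10), and it was the single row that did. The 10 rows higher at both days lay opposite Ildr2, Mfsd12, Gas1, Arf6, Hist1h2af, H2afx, Klhl38, Mab21l1 and Klhl21, or in the case of Gm15419 opposite no gene. Unrelated lists of these sizes would share 2.12 rows higher and 1.04 lower, a figure that does not allow for the vehicle libraries used by both. Across genes, which are not independent replicates, the changes at both days had a Pearson r of 0.367 and a Spearman rho of 0.355. Over 100 simulations, unchanged groups gave a mean r of 0.475 and rho of 0.448, because both changes share the vehicle libraries. The covariance was 0.0779 against a simulated 0.0548, and 62.4% of rows had the same sign against 65.9%. With separate vehicle libraries for each day, and so fewer in each comparison, r lay between 0.0973 and 0.179 over 6 ways of dividing them. In all 6, edgeR called 0 rows higher and 0 lower at both days, with 1 to 254 calls at day 5 and 0 to 468 at day 10.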

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

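The 3 tests of which strand the counts fall on were chosen after the result was seen, and the GC and CT010467.2 alternatives were added after the data had been examined.

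The direct edgeR test of day 10 against day 5, which is the difference of their changes against vehicle, called 1337 rows. With the CT010467.2 share as a covariate these changes had a median ratio of 0.674 to those without (95% interval over rows 0.660 to 0.691), 98.8% kept their sign, and the median size went from 0.73 to 0.49 while the median SE rose from 0.18 to 0.23. The calls fell to 2, by smaller changes and by lost precision. These rows were chosen for large changes without the covariate, which can by itself lower the ratio. The 14 rows opposite histone genes mostly kept their size, with a median ratio of 0.901 (0.775 to 1.19), a median log2 fold change of -1.13 before and -0.99 after, and a median SE that rose from 0.20 to 0.28, so their calls ended mainly by lost precision. The 2 calls left did not shrink, as Gm44297, opposite Hist1h2af, went from -1.20 to -1.39 and 4930558J22Rik, opposite Hist1h4b, from -1.13 to -1.34 (edgeR adjusted p 0.0182 each with the covariate). How much of the change in other rows is library composition stays open. A further 22 values stood apart from the other 3 libraries of their group, by a gap test that chance alone meets in about 1 of 20 groups. That is 19.65 of the 393 groups tested, so 22 is close to what chance gives. Vehicle replicate 4 had 3227138 counts, and day 10 replicate 2 had 0.775% of counts in satellite rows. In mean log2 CPM of gene lists, these were antigen presentation in vehicle replicate 4 (5.00), brain and glia in day 10 replicate 2 (5.27), metallothioneins in day 5 replicate 6 (3.05), rows opposite skeletal muscle genes in day 10 replicate 1 (6.92), sustentacular cells and Bowman glands in day 10 replicate 5 (4.18) and vomeronasal receptors in vehicle replicate 6 (2.89).

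Day 10 replicate 1 stood apart in CPM of BE692007, opposite Ms4a6c (68.4), Gm15587, opposite Nos3 (72.5), Gm17711, opposite Abracl (31.4), and Hapln3 (3.60). Each of the 4 lay on the side of the comparison group. Day 10 replicate 2 stood apart in Olfr1396 (0), Orc2, opposite Nif3l1 (2.06), and Rusc1 (19.9). Among vehicle libraries these were Arnt (8.61) and Pim3 (4.08) in replicate 6, Ccdc152, opposite Selenop (375), in replicate 5, and Lrrc18 (19.3) in replicate 4. At day 5 they were Mrpl57 (8.49) and Vmn1r184 (7.22) in replicate 5 and Ret (17.8) in replicate 6.

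Counts were concentrated in rows opposite to abundant genes in all 12 libraries. Transcription of both strands beside normally counted genes is argued against, because over 1207 pairs the antisense row was denser than its protein-coding partner by a median log2 ratio of 5.43 (quartiles 2.71 and 7.45). Reads without strand are argued against too, because 81.4% of pairs were over 4-fold denser in the antisense row, where reads falling on either strand alike would make the pair densities about equal. A candidate explanation that remains open is that reads were assigned to the strand opposite to the RNA. The own rows of ribosomal protein genes then hold little, and they held at most 0.149% of counts in any library, but neither the strand marking of the kit nor the counting setting is given in the sources used here.

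Rows called between day 10 and vehicle shifted most in 3 of the 4 day 10 libraries, those with the largest shares of CT010467.2. The mean log2 shift from vehicle, signed by the call, was 0.866 to 1.12 in these, 0.366 in day 10 replicate 1, 0.163 to 0.252 at day 5 and -0.0613 to 0.0528 in vehicle. The rows were chosen by their distance from vehicle, which alone raises the shift of other libraries, so the smaller shifts decide nothing. Correcting the GC trend of each library shrank the called changes to a median ratio of 0.750 (95% interval over rows 0.731 to 0.767). The median size was 0.76 before and 0.58 after, with a median SE of 0.19 and 0.18. This ratio lies between the bounds set for the test, so GC content as the main cause cannot be told apart from the rest. With the CT010467.2 share as a covariate the median ratio was 0.251 (0.219 to 0.275 over rows). The median size fell from 0.76 to 0.21 while the median SE rose from 0.19 to 0.28. Intervals over rows do not cover the spread between libraries, and choosing rows by large uncorrected changes can by itself lower both ratios. All 933 calls ended, mostly because the changes shrank and also because the covariate takes precision. Differences in library composition may therefore account for much of this comparison, but a response to KDP20 that was strongest in those 3 samples stays open.

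Rows opposite histone genes were higher at day 5 than in vehicle, with a median log2 fold change of 1.00 over 14 rows. By the bound set beforehand, 168 small nuclear and nucleolar RNA rows (median -0.25, 95% interval -0.31 to -0.17) argue against a greater capture of RNA without a poly(A) tail. That bound reads own rows, which need not hold the RNA of their gene if reads were assigned to the other strand, so this explanation is not ruled out. Another candidate explanation is a larger share of dividing cells at day 5 of KDP20. The 20 rows opposite cell-cycle genes had a median of 0.38, with 17 positive but 1 called by edgeR (Gm10143, opposite Fen1, adjusted p 0.0384), at percentile 99.53 of 10000 matched sets with a median of 0.16, where the sets were drawn from rows opposite protein-coding genes and so more narrowly than first worded. Day of collection differs with exposure in this comparison and stays open, untested.

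The real division called the most rows in each of the 3 comparisons when the 8 libraries were divided into 4 and 4 in all 35 ways. A share of 1 in 35 is the smallest this test can give, so it argues against chance without excluding it. Day 10 against vehicle called 423 rows in the real division and at most 77 in the others, so 1 of 35 divisions reached the real count. The values were 656 and 27 for day 5 against vehicle and 963 and 28 for day 10 against day 5, again with 1 of 35 each. These counts come from the 8 libraries alone and differ from the reported ones for that reason.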

How the results depend on the processing

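The alternatives with GC content, CT010467.2, satellite rows, opposite rows alone and 3 day 10 libraries left out were chosen after seeing the data, and the other alternatives were planned. For day 10 against vehicle, DESeq2 (1362 calls), limma-voom (986), both scalings and both filters gave counts within 1.5 times 933. The count was 423 with the 8 compared libraries, 1701 with the replicate block (777 higher, 924 lower), 422 with GC correction (340 higher, 82 lower), of which 317 were shared with the 933, and 0 by edgeR with the CT010467.2 covariate (409 at an unadjusted p under 0.05). It was also 0 without the 3 day 10 libraries (757 unadjusted), where 1 day 10 library remained, assumed to vary like the others. With a library left out it ran from 95 to 2684. For day 5 against vehicle it was 278 without a filter, 135 with the strict filter, 514 with DESeq2, 284 with limma-voom, 656 with the 8 libraries, 33 with the block, 140 with the covariate, 172 for rows opposite protein-coding genes and 641 without the 3 libraries. With a library left out it ran from 5 to 569. For day 10 against day 5 it was 2 with the covariate (1471 unadjusted), namely Gm44297 (log2 fold change -1.39) and 4930558J22Rik (-1.34), opposite Hist1h2af and Hist1h4b, and 0 by edgeR without the 3 libraries (992 unadjusted). With a library left out it ran from 623 to 2689, and the other alternatives stayed within 1.5 times 1337. The cause of these differences was not tested. Fewer libraries or a covariate leave less information by construction. That cannot account for the higher counts at day 5 against vehicle with the 8 libraries or with the covariate.

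By own rows, the lists past camera at day 10 against vehicle were 1, and 0 with an estimated correlation, 2 with DESeq2 scaling, 2 with the strict filter and 1 to 3 with a library left out. At day 5 against vehicle they were 0 with camera and 1 with fry, and with a library left out 0 in each case. At day 10 against day 5 they were 0, 2 with the strict filter and 0 to 2 with a library left out. The correlation of changes at both days was 0.367 with DESeq2 scaling and 0.344 with the strict filter. It was 0.118, 0.0973, 0.131, 0.136, 0.109 and 0.179 when the vehicle libraries were divided. The shared vehicle then no longer adds to it, and fewer vehicle libraries in each comparison add noise that can also lower it. These effects were not separated.

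Of the 72, 42 and 80 named calls of the 3 comparisons, in the order above, 70, 41 and 80 held with DESeq2 scaling, 60, 41 and 68 with limma-voom, 35, 38 and 66 with GC correction, and 0, 32 and 2 with the covariate. Reversed under the covariate at day 10 against vehicle were CT010467.2 (-0.032), 1700034H15Rik, opposite Slc30a1 (-0.20), Ccdc39 (0.16), Cd247 (0.021), H2-DMa (-0.23), Atp2a1 (-0.010), Thra, opposite Nr1d1 (-0.45) and Gm49544 (-0.12), all short of the threshold, and the first by construction. DESeq2 gave no adjusted p for 56 of 211 named results, mostly weakly counted genes, so depth limits what it says about them.

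The replicate number was tried as a block although the labels do not pair the samples. Across genes, residuals of libraries with the same number correlated between -0.0894 and 0.124 over 5 pairs, and others between -0.118 and 0.113 over 43 pairs, so the numbers showed no pairing. With the block, 50, 11 and 40 of the named calls held.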

Other observations

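A few rows of repeats and small RNAs were higher at day 10 than in vehicle, and these classes were not tested as lists. Of 12 satellite rows, 6 were tested. The satellite rows Gm10800 (log2 fold change 2.86, edgeR adjusted p 0.0189) and Gm10801 (3.09, 0.0147) and the small RNA row Gm23935 (2.24, 0.00843) were higher, and were chosen after their values were seen. Satellite rows held 0.261% ± 0.344 of counts at day 10 against 0.0430% ± 0.0226 for vehicle (mean ± SD, n = 4). Exact permutation gave p 0.0571 and an adjusted p of 0.0779. Day 10 replicate 2 alone held 0.775% with a Wilson interval of 0.762% to 0.788%, and the other day 10 libraries held 0.0632% to 0.133%.

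Of the 4 tested rows opposite basal and squamous genes, too few for camera, most were not called over all rows. Gm49428 and Gm44342, both opposite Krt6a, were not called, with log2 fold changes of 1.44 (edgeR adjusted p 0.165) and 1.33 (0.175) at day 5 against vehicle. From day 5 to day 10 they were not called either, with -1.43 (adjusted p 0.0861) and -1.45 (0.0764). The 4 rows had a median of 1.28 at day 5 against vehicle, with 1 called over all rows and 4 over the list alone, and -1.44 from day 5 to day 10, with 1 called and 4 over the list alone.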
